A study of Homo sapiens with 6 samples.

How the data were processed

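RNA from 6 cultures of HCT116 cells, an established human colon cancer line, was measured with 1 whole-transcript expression array per culture. Per the labels, siRNA was delivered at 50 nM with a lipid reagent and cells were harvested after 48 h. Total RNA was extracted with Trizol and biotin-labelled cDNA was prepared with the WT PLUS kit. The 3 groups, a control siRNA, siH19-1 and siH19-2, had 2 arrays each. Groups and replicate numbers were taken from the sample titles.

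The deposited values were log2 signals. Per the labels, the authors made them with Affymetrix Expression Console and RMA, which corrects background, brings arrays to a common distribution and summarises the probes of each row. Versions, further parameters and the genome build were not given in the sources used here. The table held 70523 rows, of which 67528 were transcript clusters, the array's gene-level units. The other 2995 rows, control probe sets among them, stayed out of the main tests. Array medians over transcript clusters lay between 4.10 and 4.20. Gene symbols came from the platform annotation, and a RefSeq gene table was used for gene classes and for older symbols in the gene lists. Of all transcript clusters, 23781 had 1 symbol, 1543 had several and 42204 had none.

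Transcript clusters with a log2 signal of at least 5 in at least 2 arrays were tested, 24721 in all. Of these, 11715 had 1 symbol (11191 distinct genes), 834 had several and 12172 had none. For 911 of them another cluster held identical values on all 6 arrays, and 621 lay on alternate haplotypes. As a scale for this filter, 20 of 23 background probe rows had a mean under 5, with a median of 3.00 over the 23.

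A model with a coefficient per group was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). It left 3 residual degrees of freedom, moderated with 2.75 prior degrees of freedom. The mean of both siRNAs and each single siRNA were compared with the control, and siH19-2 with siH19-1. Each limma p was two-sided and adjusted by Benjamini-Hochberg over the tested transcript clusters within a comparison, with a threshold of 0.05. An SE came from this fit, and an SD was taken over the 2 arrays of a group. The number of arrays limits the precision. Tested on simulated data with the fitted spread of these arrays, the fit recovered 62.6% of changes of fold 2 with siH19-1 and 53.9% with siH19-2, and 6.9% and 2.0% of changes of fold 1.5. In that simulation far fewer clusters changed than were called in these data, and recovery at an adjusted threshold depends on that share. The percentages are therefore not the power in these data. With siH19-2, 3784 of 5203 called clusters had a fold of at least 1.5, so smaller changes were called too.

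Gene lists were tested two-sided with limma's camera at a preset inter-gene correlation of 0.01, on the cluster of highest mean for each gene, with Benjamini-Hochberg adjustment over the lists within a comparison. Camera compares a list with all other measured genes. Of 39 lists, 32 had the required 5 measured genes. Camera with an estimated correlation was run beside it, as was fry, which tests whether a list's genes move on balance in a single direction and does not compare them with other genes. With 3 residual degrees of freedom, camera with an estimated correlation could hardly call a list. It gave 0 lists at an unadjusted p under 0.05 in any comparison, also where the preset camera p was 2.16e-10 (G1/S with siH19-2). Its lack of calls therefore counts neither for nor against a list. On simulated data with 1 list shifted, camera found that list and called 0 of the other lists. That was a single simulated data set with genes drawn independently. It cannot show how often camera at the preset correlation calls lists whose genes vary together.

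The comparisons, filter, tests, gene lists, naming rule and all alternatives but those named below were fixed before the data were examined. The lists were written from general knowledge, none of them on these samples. H19 was always named. For the mean of both siRNAs the rule took the 12 largest rises and the 12 largest falls among called genes whose siH19 arrays all lay on the same side of both control arrays. For each other comparison it took 6 in each direction among called genes without overlap between the arrays compared. It also took up to 4 members per list of smallest p in the mean of both siRNAs, and all members of the RB and E2F family and of the Mediator kinase module with an unadjusted p under 0.05. For lists that were not called, the text gives only the 2 members of smallest p. Which list members are given again for a single siRNA or for the difference was chosen after their values were seen. Only clusters with 1 symbol were named, and uncharacterised loci and small RNA genes were counted but not named.

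Deviations from the group mean of same-numbered arrays correlated at 0.29 between control and siH19-1, 0.20 between control and siH19-2 and 0.20 between the siRNAs. All 3 exceeded the minimum of 0.1, so the replicate numbers were taken to pair the arrays, and a fit with replicate number as a block was run as an alternative. The main fit stayed without the block. Other alternatives were no filter, a filter at log2 6, eBayes without trend or robust, quantile normalization again, median centring, a fit of only the groups compared, array weights, a required fold of 1.5, the mean of all clusters of a gene in the list tests, and leaving out each array. After the data were seen, counting identical values once, scaling each array to its 8 labelling and hybridization controls, and setting each siRNA array against a control array of its own were added. The correlation and covariance of the siRNAs' log2 fold changes were set beside 100 simulations of unchanged groups that shared the control arrays, with arrays drawn independently. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.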

Results

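Expression was measured in 6 arrays of HCT116 colon cancer cells, 2 with a control siRNA, 2 with siH19-1 and 2 with siH19-2. Both siRNAs were directed at H19, an imprinted long noncoding RNA that is also the precursor of miR-675. The comparisons address which transcripts change when H19 is targeted, and whether both siRNAs change the same ones. Across tested transcript clusters, arrays of a group correlated at 0.9925 to 0.9945 and arrays of different groups at 0.9744 to 0.9873. The first principal component held 51.5% of the variance and set siH19-2 apart, and the second held 25.1% and parted control from siH19-1.

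H19 itself was not lower in the arrays labelled siH19-1 or siH19-2. Its log2 signal was 4.92 ± 0.14 (SD, n = 2) in control arrays, 4.95 ± 0.06 (SD, n = 2) with siH19-1 and 4.98 ± 0.05 (SD, n = 2) with siH19-2. For the mean of both siRNAs the H19 log2 fold change was 0.045 (SE 0.10, 95% interval -0.20 to 0.29, limma adjusted p = 0.822), and the lower end of the interval is a fold of 0.87 in signal. It was 0.025 with siH19-1 (limma adjusted p = 0.938), 0.065 with siH19-2 (0.738) and 0.040 for siH19-2 against siH19-1 (0.844). The transcript cluster is annotated to both H19 and MIR675. Among 47 marker genes of other cell types, 4 had a mean signal at or above the 4.95 of H19, and their median was 3.72. The H19 mean lay under the filter value of 5. Its cluster passed the filter through control replicate 2 and siH19-2 replicate 2, each at 5.02. It ranked at percentile 3.2 of the tested clusters, a set that the filter cuts near this value, and at percentile 64.5 of all transcript clusters. The upper quartile of the marker means was 3.97, and background probe rows had means up to 5.99. At a signal this low a fall may not show, so the interval does not bound a change of H19 RNA. No fall of H19 was detectable in this signal, so the directions given for the siRNAs rest on the array labels. Its sign was negative without control replicate 1 (-0.055 for the mean of both siRNAs) and with scaling to the control probes (-0.115), and it did not pass in either.

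**Figure D1:**
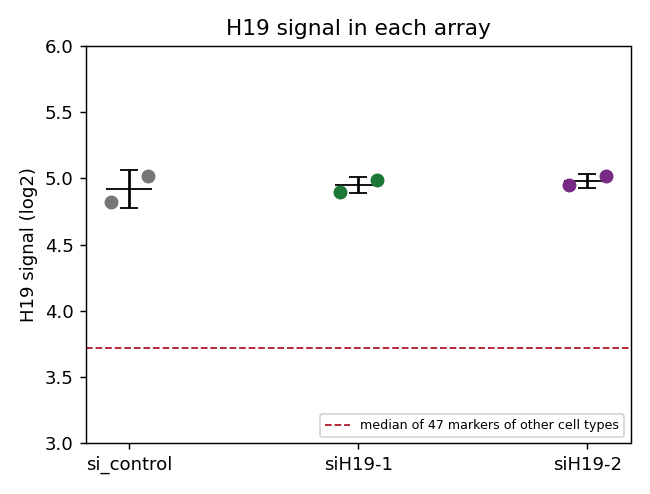
H19 signal (vertical axis, log2) in each array by group, with 2 points per group, a line at the mean and error bars of 1 SD. The arrays lie between 4.82 and 5.02, and the dashed line marks the median of 47 marker genes of other cell types at 3.72.

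In the mean of both siRNAs against control, the vitamin D hydroxylase gene CYP24A1, the E-cadherin gene CDH1 and PMAIP1, which encodes the pro-apoptotic protein NOXA, were among the largest rises. The Notch ligand gene JAG1, the ERK phosphatase gene DUSP6 and the transcription factor genes SOX4 and EGR1 were among the largest falls. Cell cycle and histone lists were called lower, and p53 target and cholesterol lists higher, with camera at a preset correlation. They were not called with an estimated correlation (camera adjusted p = 0.789 for each), which could hardly call a list in this design. In all, 1282 transcript clusters were higher and 1772 lower, 3054 of 24721. Over all called clusters the largest rise was 3.22 and the largest fall -3.28. Among genes that the naming rule covers, log2 fold changes of the largest rises were 2.68 for CYP24A1 (SE 0.23), 2.57 for LRRC58 (SE 0.15), 2.47 for PMAIP1 (SE 0.26), 2.33 for the kinase gene FRK and 2.27 for GPAT3 of glycerolipid synthesis. CDH1 rose by 2.26, UHMK1 by 2.25, TULP3 by 2.16, the receptor kinase gene AXL by 2.14, POMK by 2.10, LMAN1, a cargo receptor of the secretory pathway, by 1.99 and ENPP5 by 1.98. Log2 fold changes of the largest falls under that rule were -3.28 for JAG1 (SE 0.30), -2.82 for NDUFAB1, the mitochondrial acyl carrier protein gene (SE 0.09), -2.77 for ADAM19, -2.56 for NETO2, -2.51 for DUSP6 and -2.46 for SOX4. PHLDB2 was at -2.36, EGR1 at -2.34, ZNF704 at -2.23, JMJD8 at -2.10, CSRP2 at -1.90 and ARRDC4 at -1.87. Limma adjusted p for these 24 genes lay between 0.00245 for NDUFAB1 and 0.0118 for DUSP6, and all 24 passed without each of the arrays. The count was 636 without control replicate 1 (367 higher and 269 lower) and 1772 without control replicate 2 (550 higher and 1222 lower), so which direction was more frequent turned on a single control array. The count was 865 and 939 without siH19-1 replicates 1 and 2, 979 and 1292 without siH19-2 replicates 1 and 2, and 1489 with no filter. Scaling to the control probes shifted the median of all clusters by -0.16 (-0.07 with siH19-1, -0.25 with siH19-2, -0.17 between them) and gave 765 higher and 3273 lower.

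**Figure D2:**
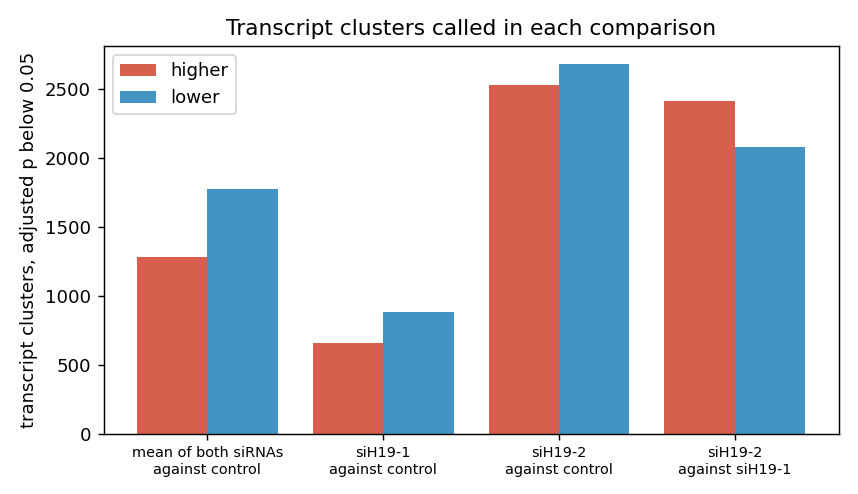
Transcript clusters with a limma adjusted p below 0.05 (vertical axis, from 0) that were higher or lower in each of 4 comparisons. siH19-2 against control had 2527 higher and 2676 lower, and siH19-1 against control had 656 and 881.

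Of 32 gene lists, 6 were called lower and 6 higher in the mean of both siRNAs. With an estimated correlation none of the 12 was called (adjusted p = 0.789 for each, 0 lists at an unadjusted p under 0.05), a version too weak in this design to decide. With fry none was called, with 11 at an unadjusted p under 0.05. Of the 12, G2/M, histone and cholesterol lists were called with each siRNA alone. The p53, unfolded protein response, NRF2 and metallothionein lists were called with siH19-1 and not with siH19-2 (adjusted p = 0.0959, 0.200, 0.439 and 0.0959). The G1/S, RB and E2F, Wnt target and ribosomal lists were called with siH19-2 and not with siH19-1 (0.605, 0.216, 0.216 and 0.385), and the lysosome list with neither (0.160 with siH19-1, 0.114 with siH19-2). A call with 1 siRNA only is not a difference between them. Compared directly, the G1/S (camera adjusted p = 6.59e-09) and ribosomal (0.0493) lists differed. The p53 (0.338), unfolded protein response (0.239), NRF2 (0.104), metallothionein (0.638), RB and E2F (0.0978) and Wnt target (0.117) lists did not pass. Of 33 measured genes of G1/S and DNA replication, 15 fell, 0 rose and 18 did not pass (median log2 fold change -0.42, camera adjusted p = 9.19e-06), and adjusted over the list alone 20 fell and 1 rose. With siH19-1 alone 2 of the 33 fell (median -0.15). The cell cycle transcription factor gene MYBL2 (-1.81), the cyclin gene CCNE2 (-1.17), and GINS2 (-1.01) and CDC45 (-0.76) of the replicative helicase fell. Of 34 G2/M and mitosis genes 9 fell and 0 rose (median -0.42, camera adjusted p = 3.76e-04), 13 and 0 adjusted over the list alone. FOXM1, which drives mitotic genes (-1.36), the proliferation marker gene MKI67 (-1.33), CCNB1 (-1.16) and the centromere gene CENPA (-0.92) fell. Of 12 replication-dependent histone genes 6 fell and 0 rose (median -0.62, camera adjusted p = 7.61e-04), 11 and 0 adjusted over the list alone, with H2BC11 at -1.30, H2BC17 at -1.05, H1-4 at -0.95 and H2BC12 at -0.73. With scaling to the control probes the medians of these 3 lists were -0.58, -0.58 and -0.78.

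Of 22 genes of the RB and E2F family 5 fell and 1 rose (median -0.25, camera adjusted p = 0.0345), 9 and 2 adjusted over the list alone. CDK4 (-1.09), E2F8 (-1.04), TFDP1 (-0.94), E2F7 (-0.93) and RBL1 (-0.73) fell, and the CDK inhibitor gene CDKN1A rose (0.61). E2F7 was at 0.02 with siH19-1 (adjusted p = 0.934) and -1.88 with siH19-2. Of the 16 members that did not pass, those named by the rule were CCND1 (-0.74), RB1 (-0.52), RBL2 (-0.44), E2F1 (-0.36), E2F2 (-0.28), CCND3 (-0.22) and CDK6 (0.58). CCND1 was at -0.41 without control replicate 1 and -1.08 without control replicate 2, and RBL2 at -0.18 and -0.70. With the replicate block CCND1 (adjusted p = 0.0311), RB1 (0.0183), E2F1 (0.0471) and CDK6 (0.0205) passed. Of 15 Wnt/beta-catenin targets 5 fell and 0 rose (median -0.40, camera adjusted p = 0.0305), 6 and 0 adjusted over the list alone, with SOX4 at -2.46, CD44 at -1.67, BMP4 at -1.33 and ZNRF3 at -0.55. Of 9 metallothionein and metal response genes 3 fell and 0 rose (median -0.58, camera adjusted p = 0.0310), 7 and 0 adjusted over the list alone. MT1X (-1.29), MT1F (-1.29) and MT1E (-0.70) fell, and MT1M (-0.42) did not pass. Without control replicates 1 and 2, MT1X was at -0.85 and -1.73, MT1F at -0.77 and -1.81 and MT1E at -0.46 and -0.95. With scaling to the control probes the medians were -0.41 for the RB and E2F list, -0.56 for Wnt targets and -0.74 for metallothioneins. Without control replicate 1 the RB and E2F call (adjusted p = 0.0598) and the Wnt target call (0.0786) were lost. With the filter at log2 6 the RB and E2F (0.0754) and metallothionein (0.0522) calls were lost.

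Of 24 p53 targets 5 rose and 0 fell (median 0.20, and 0.04 with scaling to the control probes, camera adjusted p = 0.00333), 6 and 0 adjusted over the list alone, with TP53INP1 at 0.80, RRM2B, a ribonucleotide reductase subunit gene, at 0.74, TRIAP1 at 0.67 and CDKN1A at 0.61. Of 20 cholesterol synthesis and uptake genes 6 rose and 0 fell (median 0.16, and 0.00 with scaling to the control probes, camera adjusted p = 0.00601), 7 and 1 adjusted over the list alone, with HMGCS1 and SQLE at 1.14, DHCR7 at 0.97 and CYP51A1 at 0.75. Of 21 unfolded protein response genes 3 rose and 0 fell (median 0.24, and 0.09 with scaling to the control probes, camera adjusted p = 0.0233), 3 and 0 adjusted over the list alone. DNAJC3 (0.92), SYVN1 (0.63) and CANX (0.55) rose, and DNAJB11 (0.43) did not pass. The ribosomal protein list was called higher with 0 of 24 members past the threshold over all clusters or adjusted over the list alone (median 0.13, camera adjusted p = 0.0137), and with scaling to the control probes its median was -0.03 (adjusted p = 0.0501). Members were at 0.33 (RPL7), 0.29 (RPS19), 0.27 (RPS6, with 0.36 and 0.18 without control replicates 1 and 2) and 0.24 (RPS14). With that scaling CDKN1A (adjusted p = 0.0547), TRIAP1 (0.0514), CANX (0.0764) and SYVN1 (0.0677) did not pass. The unfolded protein response call was lost without control replicate 2 (0.0753) or siH19-2 replicate 2 (0.0550).

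Of 17 NRF2 and oxidative stress genes 4 rose and 3 fell (median 0.27, and 0.10 with scaling to the control probes, camera adjusted p = 0.0334), 7 and 3 adjusted over the list alone. The thioredoxin reductase gene TXNRD1 (1.06), the malic enzyme gene ME1 (0.96) and the ferritin gene FTL (0.83) rose, and PGD of the pentose phosphate pathway fell (-1.45). Of 20 lysosome and autophagy genes 2 rose and 3 fell (median 0.21, and 0.05 with that scaling, camera adjusted p = 0.0465), 3 and 3 adjusted over the list alone. LAMP2 of the lysosomal membrane (1.00) and the autophagy receptor gene SQSTM1 (0.69) rose, and the cathepsin gene CTSZ (-0.62) and the channel gene MCOLN1 (-0.45) fell. The NRF2 call was lost without control replicate 1 (0.128) or siH19-1 replicate 2 (0.0588), with no filter (0.0751), the filter at log2 6 (0.0522), quantile normalization (0.0604) and median centring (0.0529). The lysosome call was lost without control replicate 1 (0.0598), control replicate 2 (0.0511), siH19-1 replicate 2 (0.0593) or siH19-2 replicate 2 (0.0550), and with no filter (0.0851).

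**Figure D3:**
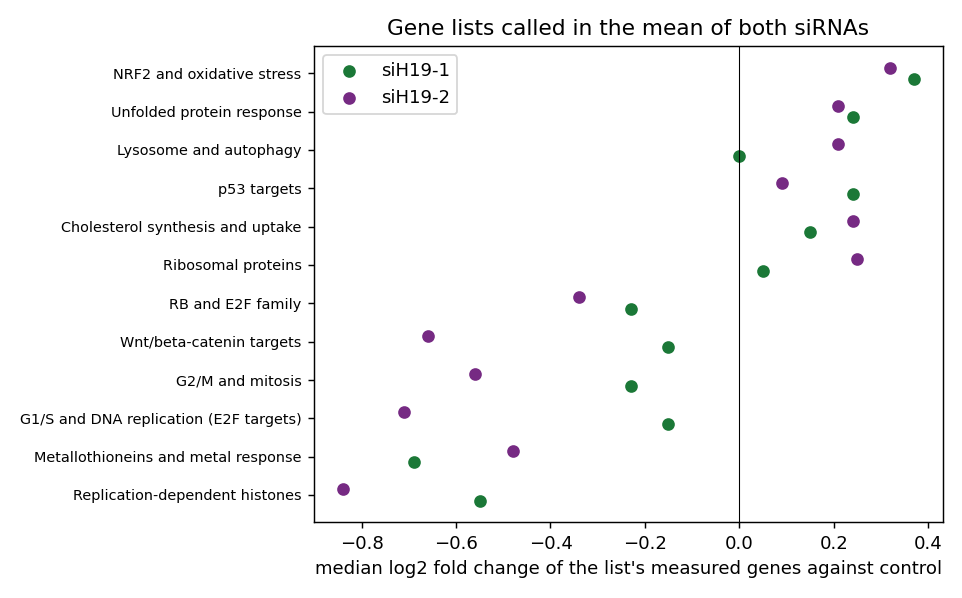
Median log2 fold change against control (horizontal axis) of the measured genes of the 12 lists called in the mean of both siRNAs, with a point for siH19-1 and a point for siH19-2. The G1/S list lies at -0.15 with siH19-1 and -0.71 with siH19-2, and with scaling to the control probes the ribosomal protein median turns negative in the mean of both siRNAs (-0.03).

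The other 20 lists tested were not called in the mean of both siRNAs. Of 24 Wnt pathway components (adjusted p = 0.0547) 2 rose and 4 fell, 3 and 10 adjusted over the list alone, with the receptor genes FZD3 (-1.62) and FZD6 (-1.44) among the falls. Of 12 TGF-beta/SMAD response genes (0.0511) 2 rose and 1 fell, 3 and 1 adjusted over the list alone, with the receptor gene TGFBR2 (1.33) and CCN1 (0.66) rising. Of 22 epithelial adhesion and keratin genes (0.0583) 3 rose and 2 fell, 7 and 2 adjusted over the list alone, with CDH1 (2.26) rising and the desmosomal gene DSG2 (-1.18) falling. The median of that list was 0.12, and -0.04 with scaling to the control probes. Of 13 interferon-stimulated genes (0.0704) 3 rose and 1 fell, 7 and 2 adjusted over the list alone, with DDX60 at 0.95 and IFIT5 at -0.61. With the replicate block the TGF-beta (0.0294) and epithelial (0.0361) lists were called. The TGF-beta list was also called without siH19-1 replicate 1 (0.0182), siH19-2 replicate 1 (0.0153) or control replicate 2 (0.0196), and the epithelial list without control replicate 1 (0.0423) or siH19-2 replicate 1 (0.0375). The interferon list was called without control replicate 2 (0.0452), and the Wnt component list with no filter (0.00196). Scaling to the control probes gave calls for the TGF-beta (0.0109), epithelial (0.0109) and interferon (0.0292) lists, the filter at log2 6 for the TGF-beta list (0.0352) and quantile normalization for the epithelial list (0.0376).

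Among lists tied to H19, 1 of 10 reported miR-675 targets rose and 2 fell (adjusted p = 0.842), 2 and 3 adjusted over the list alone, with the growth factor receptor gene IGF1R at -1.43 and SMAD1 at -0.52. Of 17 reported let-7 targets 1 rose and 2 fell (0.841), 2 and 3 adjusted over the list alone, with THBS1 at 0.88 and IGF2BP3 at -1.08. Of 9 imprinted genes 2 rose and 2 fell (0.841), 2 and 3 adjusted over the list alone, with PLAGL1 at 0.99 and PHLDA2 at -1.05. Of 6 genes that neighbour H19, 1 fell (0.641), 2 adjusted over the list alone. That gene was PHLDA2, and NAP1L4 (-0.47) did not pass, but did with the replicate block (adjusted p = 0.0317), quantile normalization (0.0206), median centring (0.0277), scaling to the control probes (0.0125) and without control replicate 2 (0.0486). Of 17 IGF and insulin signalling genes 3 rose and 1 fell (0.471), 4 and 3 adjusted over the list alone, with RICTOR at 0.85 and IGF1R as the fall. Of 7 Mediator kinase module genes MED13 rose (0.94) and CDK8 fell (-1.39), and adjusted over the list alone 1 rose and 2 fell (0.472). MED13L (-0.42) did not pass, but did with the replicate block (adjusted p = 0.0341), eBayes without trend (0.0430), quantile normalization (0.0226), median centring (0.0312) and scaling to the control probes (0.0163). CDK19 (-0.32, with -0.21 and -0.43 without control replicates 1 and 2) passed with that scaling alone among the alternatives (0.0284). Of 9 genes of the RNA-silencing list EIF2AK2 rose (0.47) and DROSHA fell (-0.49), 2 and 3 adjusted over the list alone (0.842). EIF2AK2 encodes PKR, a kinase activated by double-stranded RNA and not itself a silencing factor. It did not pass with scaling to the control probes (adjusted p = 0.159).

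In the signalling and stress lists, 6 of 20 ERK immediate-early and feedback genes fell and 0 rose (adjusted p = 0.159), 7 and 0 adjusted over the list alone, led by DUSP6 and EGR1. That list was called without control replicate 2 (0.0196) and with no filter (0.00851). Of 22 apoptosis regulators 4 rose and 0 fell (0.140), 5 and 0 adjusted over the list alone, with PMAIP1 and the cytochrome c gene CYCS (1.62). Of 11 EMT and mesenchymal genes 2 rose and 2 fell (0.780), 3 and 2 adjusted over the list alone, with AXL (2.14) and the integrin gene ITGAV (1.41) as the rises. Of 24 ATF4 and amino acid response genes SLC7A1 fell (-1.23) and 0 rose (0.0804), and adjusted over the list alone 3 rose and 2 fell. The ATF4 list was called without siH19-2 replicate 1 (0.00204) and with scaling to the control probes (0.0292), and SHMT2 (-0.40) passed with the replicate block (adjusted p = 0.0407). Of 17 heat shock genes 0 passed over all clusters or adjusted over the list alone (0.243, and 0.0447 with no filter), with HSF1 at -0.48 and HSPA4L at -0.65, which passed with the replicate block (adjusted p = 0.0363). HSPA4L was at -0.37 without control replicate 1 and -0.93 without control replicate 2.

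In the metabolic lists, 4 of 25 hypoxia and glycolysis genes rose and 2 fell (adjusted p = 0.189), 4 and 3 adjusted over the list alone, with the glucose transporter gene SLC2A3 at 1.70 and BNIP3L at 0.66. Of 18 fatty acid synthesis genes 2 rose and 0 fell (0.218), 2 and 0 adjusted over the list alone, namely ME1 (0.96) and ACACA (0.74). Of 27 MYC target and ribosome biogenesis genes 1 rose and 2 fell (0.189, and 0.0172 with no filter), 1 and 5 adjusted over the list alone, with TFRC at 0.50 (1.01 with siH19-1 and -0.02 with siH19-2) and NOP58 at -0.56 (0.01 and -1.12), and TFRC did not pass with scaling to the control probes (0.0984). Of 27 oxidative phosphorylation genes 0 passed over all clusters or adjusted over the list alone (0.841), with UQCRC2 at -0.35 and NDUFB10 at -0.33, which passed with the replicate block (adjusted p = 0.0491). The medians of the let-7 (-0.02), EMT (-0.12), fatty acid (-0.02) and IGF (-0.02) lists were negative while the test pointed up. The means of the EMT (0.12), fatty acid (0.10) and IGF (0.02) lists were positive and the let-7 mean (-0.06) was negative. Too few genes passed the filter to test 7 lists. NF-kB had 4, of which NFKB1 fell (-0.57, with -0.36 and -0.78 without control replicates 1 and 2) and NFKBIA (-0.41) did not pass, and intestinal differentiation had 4, of which KLF5 (-0.41, adjusted p = 0.0315 with the replicate block) and CA2 (0.21, with 0.12 and 0.29 without control replicates 1 and 2) did not pass. Fibroblast markers COL1A1 (0.31) and ACTA2 (0.11), the leukocyte marker CD68 (0.47) and the endothelial marker ESAM (0.28) did not pass in the mean of both siRNAs, and mitochondrially encoded, neuronal and hepatic genes had 0 measured.

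Of 93 named genes called in the mean of both siRNAs, 57 were also called with each siRNA alone, 28 with siH19-2 only, 5 with siH19-1 only and 3 with neither. These genes were picked by size of change or p in that mean, so the shares are not those of all clusters. Over all clusters 3054 were called in the mean and 860 in the same direction with both siRNAs. In 4 of them the siRNAs differed in sign, namely E2F7, NOP58, TFRC and DSG2 (0.09 with siH19-1 and -2.44 with siH19-2), so those means came from 1 siRNA. MYBL2 (-0.38 and -3.24), CCN1 (0.18 and 1.15) and RRM2B (1.29 and 0.19) were not called with siH19-1 (adjusted p = 0.261 and 0.466) or, for RRM2B, with siH19-2 (0.239). Of the 93 calls, 54 passed without each of the arrays and 39 were lost without at least 1 of them. The highest limma adjusted p among the fits that lost the call is given for each gene. Without any 1 of the 6 arrays, the call was lost by CDKN1A (0.0777), TRIAP1 (0.0961), DROSHA (0.146), EIF2AK2 (0.117), SMAD1 (0.0976), CYP51A1 (0.0828), CANX (0.0725), SYVN1 (0.120), NOP58 (0.0902), TFRC (0.149) and MCOLN1 (0.107). Lost without control replicate 1 was the call of CCNE2 (0.0583), TFDP1 (0.0514), RRM2B (0.0505), PHLDA2 (0.0594), HMGCS1 (0.0513), SQLE (0.0626), TXNRD1 (0.0543) and CTSZ (0.0531). Without any 1 array other than control replicate 2, the call was lost by CCNB1 (0.0960), NFKB1 (0.129), H2BC17 (0.0777), MT1E (0.122) and MT1F (0.114). Lost without control replicate 1, control replicate 2, siH19-1 replicate 1 or siH19-1 replicate 2 was the call of CDK4 (0.102), CD44 (0.103), SLC7A1 (0.162) and SQSTM1 (0.0658). Without siH19-1 replicate 1, siH19-1 replicate 2, siH19-2 replicate 1 or siH19-2 replicate 2, the call was lost by H2BC11 (0.0716) and MT1X (0.0844). Lost without control replicate 1, siH19-1 replicate 1, siH19-1 replicate 2 or siH19-2 replicate 1 was the call of CCN1 (0.0853) and H2BC12 (0.0578). Without any 1 array other than siH19-2 replicate 2, the call was lost by ZNRF3 (0.0804) and BNIP3L (0.0725). Lost without any 1 array other than siH19-1 replicate 1 was the call of TP53INP1 (0.0863) and IFIT5 (0.0909). Without control replicate 1, control replicate 2, siH19-1 replicate 1 or siH19-2 replicate 1, the call was lost by ACACA (0.0617). Lost without control replicate 1, control replicate 2, siH19-1 replicate 2 or siH19-2 replicate 1 was the call of RBL1 (0.0602). Without any 1 array other than control replicate 1, the call was lost by DNAJC3 (0.0664). NFKB1 (0.0513 and 0.0568), SLC7A1 (0.0508 and 0.0843), TFRC (0.0511 and 0.0684) and MT1E (0.0503 and 0.0515) lost their calls with robust eBayes and with array weights. With array weights DROSHA (0.0593) and SYVN1 (0.0505) also lost theirs, and EIF2AK2 did with quantile normalization (0.0587). Among genes that had not passed, CCND1, CDK6, SHMT2, HSPA4L, MT1M and CD68 passed with quantile normalization (0.0147, 0.0194, 0.0311, 0.0246, 0.0429 and 0.0469) and with median centring (0.0393, 0.0249, 0.0302, 0.0358, 0.0420 and 0.0449). DNAJB11 did so too (0.0425 and 0.0374), and RPL7 with median centring (0.0414). Scaling to the control probes passed CCND1 (0.010), RB1 (0.0127), RBL2 (0.0335), E2F1 (0.0496), SHMT2 (0.0203), HSF1 (0.0412), HSPA4L (0.0103), KLF5 (0.0424) and MT1M (0.0194). SHMT2 passed with eBayes without trend (0.0444) and robust eBayes (0.0475), and CCND1 (0.0272) and HSPA4L (0.0286) without control replicate 2.

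With siH19-1 alone, the largest rises among genes that the naming rule covers were in UHMK1 (log2 fold change 2.99, SE 0.18), TULP3 (2.87), LRRC58 (2.59), the translation factor gene EIF5A2 (2.43), PMAIP1 (2.31) and the carboxypeptidase gene CPA4 (2.28). NETO2 (-3.18, SE 0.21), JAG1 (-3.00), the chromatin remodelling gene SS18 (-2.71), SOX4 (-2.59), PHLDB2 (-2.58) and EGR1 (-2.49) fell most among genes under that rule. Over all called clusters the largest rise was 3.72 and the largest fall -3.19. In all, 656 transcript clusters were higher and 881 lower. Without siH19-1 replicate 1 or 2 the limma fit called 0, with 3939 and 3805 at an unadjusted p under 0.05, so none of these 12 genes passed (highest adjusted p from 0.0897 to 0.119), and CPA4 also did not pass without control replicate 1 (adjusted p = 0.0503) or 2 (0.0520). The total of 1537 was 257 without control replicate 1 (142 higher and 115 lower), 770 without control replicate 2 (257 higher and 513 lower), 551 without either siH19-2 array (271 higher and 280 lower), 557 in a fit of only these 2 groups and 607 with no filter (285 and 322). Median centring gave 1030 higher and 1009 lower, and scaling to the control probes 561 higher and 1229 lower.

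Of the lists, 8 were called higher and 4 lower with siH19-1, 0 of them with an estimated correlation (adjusted p = 0.859 each, 0 at an unadjusted p under 0.05) or with fry (7 at an unadjusted p under 0.05). Higher were p53 targets (4 of 24 rose, median 0.24, camera adjusted p = 0.00116), NRF2 genes (5 of 17 rose and 1 fell, median 0.37, 0.00212), the unfolded protein response (3 of 21 rose and 1 fell, median 0.24, 0.00212), cholesterol synthesis (4 of 20 rose, median 0.15, 0.00804), fatty acid synthesis (3 of 18 rose, median 0.19, 0.00804) and hypoxia and glycolysis (3 of 25 rose and 1 fell, median 0.20, 0.00804). Interferon-stimulated genes (1 of 13 rose, median 0.32, 0.0186) and the TGF-beta response (1 of 12 rose, median 0.27, 0.0186) were also called higher. Adjusted over the list alone, these 8 lists had 4, 10, 3, 5, 5, 4, 4 and 1 rises and 0, 2, 1, 0, 2, 1, 1 and 0 falls. With scaling to the control probes their medians were 0.17, 0.30, 0.16, 0.08, 0.12, 0.13, 0.25 and 0.20. Called lower were histones (1 of 12 fell, median -0.55, 0.00212), metallothioneins (0 of 9 fell, median -0.69, 0.0177), ERK feedback genes (3 of 20 fell, median -0.32, 0.0186) and G2/M genes (4 of 34 fell, median -0.23, 0.0240), with 6, 8, 7 and 7 falls and 0, 1, 0 and 0 rises adjusted over the list alone. RRM2B (1.29), CDKN1A (0.74), FTL (1.04), ME1 (1.06), DNAJC3 (1.05), SYVN1 (0.94), CANX (0.78), HMGCS1 (1.26) and TGFBR2 (1.22) rose. Outside the called lists CYCS (1.76), THBS1 (1.06), TFRC (1.01) and the leukocyte marker CD68 (1.02, adjusted p = 0.0205) rose and BMP4 (-1.47) fell. Without control replicate 1 the G2/M (0.129), interferon (0.0635), TGF-beta (0.129) and ERK (0.0859) calls were lost, without siH19-1 replicate 1 the interferon call (0.0554), and without siH19-1 replicate 2 the G2/M (0.237) and TGF-beta (0.232) calls. The TGF-beta call was also lost with no filter (0.124) and the interferon call with the filter at log2 6 (0.102). With no filter the RB and E2F (0.0216) and Wnt component (0.00542) lists were called lower, and without control replicate 2 the Wnt target list (0.0403). Heat shock genes were called higher without control replicate 1 (0.0229) or siH19-1 replicate 2 (0.0491). None of these 14 genes passed without each of the arrays, and the highest adjusted p is given for each. Without siH19-1 replicate 1 or siH19-1 replicate 2, the call was lost by RRM2B (0.0924), FTL (0.0924), TGFBR2 (0.0959), ME1 (0.125) and CYCS (0.102). Lost without control replicate 1, siH19-1 replicate 1 or siH19-1 replicate 2 was the call of THBS1 (0.0959) and BMP4 (0.119). Without control replicate 1, control replicate 2, siH19-1 replicate 1 or siH19-1 replicate 2, the call was lost by HMGCS1 (0.116) and CD68 (0.128). Lost without any 1 of the 6 arrays was the call of SYVN1 (0.151), TFRC (0.131) and CDKN1A (0.166). Without any 1 array other than control replicate 2, the call was lost by CANX (0.130). Lost without any 1 array other than control replicate 1 was the call of DNAJC3 (0.155). In a fit of only these 2 groups CANX (0.0543), DNAJC3 (0.0637), SYVN1 (0.0533), TFRC (0.0531) and CDKN1A (0.0728) did not pass. The siH19-2 arrays enter this comparison only through the estimate of the spread, so calls lost without them turn on that estimate.

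With siH19-2 alone, CYP24A1 (log2 fold change 3.85, SE 0.27) and ARRDC3, which encodes an arrestin-domain protein (3.85, SE 0.37), rose most among genes that the naming rule covers, followed by FRK (3.74), CDH1 (3.09), the lipase gene LIPH (2.79) and PMAIP1 (2.64). JAG1 (-3.55, SE 0.34), LRRC59 of the endoplasmic reticulum (-3.46), ADAM19 (-3.27), MYBL2 (-3.24), NDUFAB1 (-3.16) and TMED2 of vesicle traffic (-3.01) fell most among genes under that rule. Over all called clusters the largest fall was -3.64. In all, 2527 transcript clusters were higher and 2676 lower. The total of 5203 was 3209 without control replicate 1 (1879 higher and 1330 lower), 3437 and 3432 without siH19-1 replicates 1 and 2, 1285 without siH19-2 replicate 1 (605 higher and 680 lower), 2045 without siH19-2 replicate 2 (961 and 1084), 3434 in a fit of only these 2 groups and 3108 with no filter (1497 and 1611). Without control replicate 2 it was 3655 (1395 higher and 2260 lower). The replicate block gave 3416 higher and 3165 lower, and scaling to the control probes gave 1246 higher and 4996 lower.

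Of the lists, 6 were called lower and 3 higher with siH19-2, 0 of them with an estimated correlation (adjusted p = 0.889 each, 0 at an unadjusted p under 0.05). Fry called G1/S genes (adjusted p = 0.0170), RB and E2F genes (0.0466) and histones (0.0466). Of 33 G1/S genes 22 fell and 0 rose (median -0.71, camera adjusted p = 6.93e-09), 28 adjusted over the list alone, with GINS2 at -1.54. Of 34 G2/M genes 16 fell and 0 rose (median -0.56, 1.32e-04), 18 adjusted over the list alone, with FOXM1 at -2.01 and MKI67 at -1.89. Of 22 RB and E2F genes 9 fell and 1 rose (median -0.34, 0.0320), 11 and 1 adjusted over the list alone, with E2F7 at -1.88, RBL1 at -1.05, RB1 at -0.98, E2F1 at -0.43 and E2F2 at -0.37. Histones (9 of 12 fell and 1 rose, median -0.84, 0.00390, H2BC11 at -1.88), Wnt targets (7 of 15 fell, median -0.66, 0.0139, CD44 at -2.18) and heat shock genes (7 of 17 fell, median -0.52, 0.0139, STIP1 at -1.38 and HSF1 at -1.01) were called lower, with 11, 9 and 9 falls and 1, 0 and 1 rises adjusted over the list alone. With scaling to the control probes the medians of the 6 lists called lower were -0.96, -0.81, -0.59, -1.09, -0.91 and -0.76. Ribosomal proteins (4 of 24 rose, 0.00390, with a median of 0.25 that became 0.00 with scaling to the control probes) were called higher, as were cholesterol genes (7 of 20 rose and 1 fell, 0.0208, with a median of 0.24 that became -0.01) and ATF4 genes (4 of 24 rose and 2 fell, 0.0208, with a median of 0.34 that became 0.10). These 3 lists had 4, 7 and 7 rises and 0, 2 and 2 falls adjusted over the list alone. SQLE was at 1.34 and RPS19 at 0.75, which did not pass with that scaling (adjusted p = 0.0802). CDK8 (-2.07), DSG2 (-2.44), PGD (-2.29) and PHLDA2 (-1.46) fell, and SLC2A3 (2.21), ITGAV (1.92) and MED13 (1.45) rose. The fibroblast marker COL1A1 (0.46, adjusted p = 0.0268) and the endothelial marker ESAM (0.38, adjusted p = 0.0391) also rose, but not with scaling to the control probes (0.369 and 0.564) or in a fit of only these 2 groups (0.0577 and 0.0726). ESAM also did not pass with quantile normalization (0.0590), median centring (0.0566) and array weights (0.0512). The RB and E2F call was lost without control replicate 1 (0.0538) and with the filter at log2 6 (0.0577), and the ATF4 (0.261) and heat shock (0.0725) calls without siH19-2 replicate 2. The epithelial list was not called (0.0543), but was with the replicate block (0.0445), no filter (0.0358), the filter at log2 6 (0.0492), quantile normalization (0.0292), median centring (0.0360) and scaling to the control probes (0.00526). It was also called without control replicate 1 (0.0402), siH19-1 replicate 1 (0.0492), siH19-1 replicate 2 (0.0493) or siH19-2 replicate 1 (0.0317). With no filter the metallothionein (0.00706), MYC target (0.00657) and Wnt component (0.0322) lists were called lower. The metallothionein list was so without control replicate 2 (0.0142), and called higher were p53 targets without control replicate 1 (0.0194) and the unfolded protein response without siH19-2 replicate 1 (0.0249). Of 37 calls of named genes 28 passed without each of the arrays, and the highest adjusted p of the other 9 is given. Without siH19-2 replicate 1, the call was lost by H2BC11 (0.0550) and HSF1 (0.0706). Lost without any 1 of the 6 arrays was the call of E2F1 (0.187), E2F2 (0.196), COL1A1 (0.121) and ESAM (0.159). Without control replicate 1, siH19-2 replicate 1 or siH19-2 replicate 2, the call was lost by RB1 (0.104). Lost without control replicate 1 or siH19-2 replicate 2 was the call of STIP1 (0.0745). Without control replicate 2, siH19-2 replicate 1 or siH19-2 replicate 2, the call was lost by RPS19 (0.0932). E2F2 also did not pass with median centring (0.0530), and E2F1 and E2F2 did not with array weights (0.0562 and 0.0572) or in a fit of only these 2 groups (0.0720 and 0.0865). The siH19-1 arrays enter this comparison only through the estimate of the spread, so calls lost without them turn on that estimate.

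Compared directly, siH19-2 and siH19-1 differed in 4495 transcript clusters, 2414 higher and 2081 lower with siH19-2. Higher with siH19-2 were ARRDC3 (log2 fold change 3.73, SE 0.37), the protease gene PRSS8 (2.98), SS18 (2.87), FRK (2.82), the nuclear receptor gene NR4A2 (2.73) and the splicing regulator gene PTBP2 (2.64). Lower were LRRC59 (-3.94, SE 0.14), IDH3A of the citrate cycle (-3.55), MYBL2 (-2.86), MLEC (-2.70), TMED2 (-2.66) and the arginine methyltransferase gene CARM1 (-2.61). The count was 756 without siH19-1 replicate 1 (411 higher and 345 lower), 517 without siH19-1 replicate 2 (230 and 287), 574 without siH19-2 replicate 1 (276 and 298), 1319 without siH19-2 replicate 2 (675 and 644) and 2667 with no filter (1396 and 1271). Median centring gave 2273 higher and 2944 lower, and scaling to the control probes 1419 higher and 3072 lower.

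Of the lists, 5 differed between the siRNAs, 0 of them with an estimated correlation (adjusted p = 0.963 each, 0 at an unadjusted p under 0.05), and fry called G1/S genes (adjusted p = 0.0211). Of 33 G1/S genes 19 were lower and 0 higher with siH19-2 (median -0.54, camera adjusted p = 6.59e-09), 24 adjusted over the list alone, with GINS2 at -1.06, while CCNE2 (-0.54) did not pass except with median centring (adjusted p = 0.0452) or scaling to the control probes (0.0444). Of 34 G2/M genes 9 were lower and 1 higher (median -0.28, 0.0130), 12 and 1 adjusted over the list alone, with FOXM1 at -1.29, MKI67 at -1.11 and CENPA at -0.64. Of 17 heat shock genes 7 were lower and 0 higher (median -1.01, 0.00139), 11 adjusted over the list alone, with the co-chaperone gene STIP1 at -1.46 and HSF1, which drives heat shock genes, at -1.08. ATF4 genes (4 of 24, 0.0377, median 0.31, and 0.14 with scaling to the control probes) and ribosomal proteins (3 of 24, 0.0493, with a median of 0.17 that became -0.00 with scaling to the control probes, RPS19 at 0.92) were higher, 3 and 3 adjusted over the list alone. Other differences were in DSG2 (-2.53), E2F7 (-1.91), CDK8 (-1.36), RRM2B (-1.10), RB1 (-0.93), MED13 (1.02) and CDK19 (0.81). Without siH19-2 replicate 2 the G2/M (0.152), ATF4 (0.337) and ribosomal (0.0934) calls were lost, without siH19-1 replicate 1 the G2/M (0.0811) and ribosomal (0.0988) calls, and without siH19-1 replicate 2 the ATF4 (0.0620) and ribosomal (0.0589) calls. The ribosomal call was also lost with quantile normalization (0.105), median centring (0.0642), scaling to the control probes (0.118), the mean of all clusters of a gene (0.0505) and the filter at log2 6 (0.0657), which also ended the ATF4 call (0.0597). Genes that neighbour H19 were not called (0.0535), but were with the replicate block (0.0444) and without control replicate 1 (0.0494) or 2 (0.0493). With no filter the fatty acid (0.0184), hypoxia (0.0150), NRF2 (0.0184), oxidative phosphorylation (0.0187) and RB and E2F (0.0182) lists were called lower with siH19-2. Of 26 calls of named genes 15 passed without each of the arrays, and the highest adjusted p of the other 11 is given. Without siH19-1 replicate 1, siH19-1 replicate 2 or siH19-2 replicate 1, the call was lost by GINS2 (0.0539), FOXM1 (0.0521), MKI67 (0.0532), HSF1 (0.0775) and CDK8 (0.0562). Lost without siH19-1 replicate 1, siH19-1 replicate 2, siH19-2 replicate 1 or siH19-2 replicate 2 was the call of STIP1 (0.0820), RPS19 (0.0687), RB1 (0.130), CDK19 (0.0917) and CENPA (0.106). Without siH19-1 replicate 2 or siH19-2 replicate 1, the call was lost by MED13 (0.0521).

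**Figure D4:**
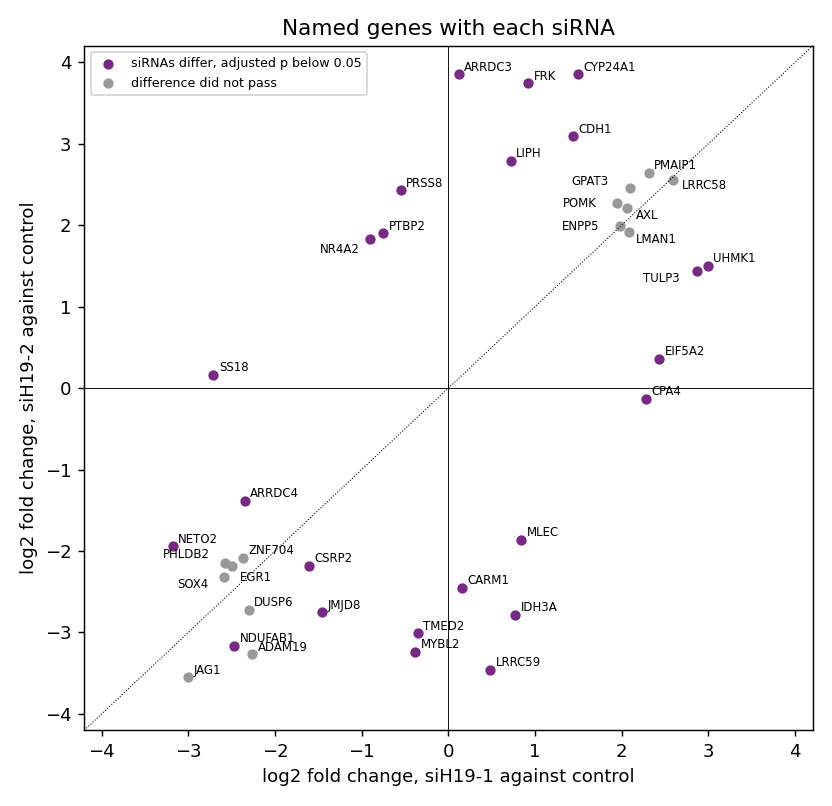
Log2 fold change against control with siH19-1 (horizontal axis) and siH19-2 (vertical axis) of the genes named for the largest changes, coloured by whether the difference between the siRNAs passed, with a dotted line of equal change. JAG1 lies near that line at -3.00 and -3.55, and SS18 far from it at -2.71 and 0.16.

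Both siRNAs changed 860 transcript clusters in the same direction, 394 higher and 466 lower. Counted as distinct genes among clusters with 1 symbol, 240 genes were higher and 316 lower with both. They included PMAIP1, LRRC58 and AXL as rises and JAG1, SOX4, EGR1 and DUSP6 as falls. Independent lists of these sizes would share 67.1 higher and 95.4 lower clusters, a reference that leaves out the noise of the shared controls. Opposite directions were called for 66 clusters, against 161.1 for independent lists, and for 115 with the replicate block. The 66 became 5 and 9 without control replicates 1 and 2, 0 with limma without either siH19-1 array (326 and 265 at an unadjusted p under 0.05), and 5 and 11 without siH19-2 replicates 1 and 2. Across clusters, which are not independent replicates, the log2 fold changes of the siRNAs correlated at 0.445 and their covariance was 0.0863. In 100 simulations of unchanged groups that shared the controls these were 0.499 and 0.0159, with arrays drawn independently and so without the pairing by replicate number. With each siRNA array set against a control array of its own, so that no array was shared, the covariance lay between 0.0407 and 0.0717 and the correlation between 0.156 and 0.321 over the 8 arrangements. In the 2 arrangements that take same-numbered arrays within each siRNA the covariance was 0.0640 and 0.0717. Of the 860 clusters, 190 also differed between the siRNAs. The 860 became 156 without control replicate 1 (64.7% higher, 55 lower), 487 without control replicate 2 (165 higher and 322 lower), 207 without siH19-2 replicate 1 (122 higher and 85 lower) and 253 without siH19-2 replicate 2 (140 higher and 113 lower). It was 296 in fits of only the groups compared (164 higher and 132 lower) and 329 with no filter. The limma count was 0 without siH19-1 replicate 1 or 2, where 1881 and 1957 had an unadjusted p under 0.05 with both siRNAs, and scaling to the control probes gave 265 higher and 792 lower.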

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

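All tests of explanations below were chosen after the results they concern were seen, except the test of a single response of different strength. H19 was not lower in the siH19 arrays (log2 fold change 0.045 for the mean of both siRNAs, limma adjusted p = 0.822). An exchange of single arrays between groups is argued against by the correlations, since the lowest within a group (0.9925) lay above the highest between groups (0.9873), although whole groups with exchanged labels would look the same. Signal in the range of background, where a fall could go unseen, stays open: 8.51% of the marker genes of other cell types had a mean at or above that of H19, and neither bound set for that share was met. That share takes the markers to be silent, yet COL1A1, ACTA2, CD68 and ESAM passed the filter, and the highest marker mean was 7.14. It therefore does not measure background alone. A knockdown that did not take place or had faded at 48 h is a further open explanation and was not tested.

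The siRNAs differed from each other in 4495 transcript clusters, by a test of the difference itself, and gave 860 calls of the same and 66 of opposite direction against control. Leaving out 1 array changed the 4495 to 4760 and 4747 (control replicates 1 and 2), 756 and 517 (siH19-1) and 574 and 1319 (siH19-2). A constant offset between arrays is argued against, since 5217 clusters differed after median centring, and so is a larger replicate spread with siH19-2, whose SD of replicate differences was 0.277 against 0.318 in control and 0.268 with siH19-1. A single response that siH19-2 evokes more strongly, as a different degree of H19 loss alone would give, stays undecided as the cause. Among 1537 clusters called with siH19-1 the change was significantly smaller or of other sign with siH19-2 in 583 (37.9%), by the direct comparison. In 111 (7.2%) it was significantly larger, and in the rest no difference was called. These clusters were picked with the siH19-1 arrays that also enter the direct comparison, so overestimated siH19-1 changes add to the 583. At most 225 of the 4495 are expected to be false calls, a bound that does not hold within the picked clusters. The counts therefore cannot decide the question. Sequence-specific effects of each siRNA on other transcripts remain open and untested, the siRNA sequences not being used here.

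The lists that differed between the siRNAs were G1/S and DNA replication (camera adjusted p = 6.59e-09), heat shock (0.00139), G2/M (0.0130), ATF4 and amino acid response (0.0377) and ribosomal proteins (0.0493). None of the 5 was called with an estimated correlation (adjusted p = 0.963 each, 0 at an unadjusted p under 0.05), which could hardly call a list in this design. Leaving out 1 array ended the G2/M call (siH19-1 replicate 1, 0.0811, and siH19-2 replicate 2, 0.152), the ATF4 call (siH19-1 replicate 2, 0.0620, and siH19-2 replicate 2, 0.337) and the ribosomal call (siH19-1 replicates 1 and 2, 0.0988 and 0.0589, and siH19-2 replicate 2, 0.0934). Of 135 genes named, 60 differed between the siRNAs with a limma adjusted p below 0.05. The 39 lower with siH19-2 had these log2 fold changes against siH19-1: LRRC59 -3.94, IDH3A -3.55, MYBL2 -2.86, MLEC -2.70, TMED2 -2.66, CARM1 -2.61, DSG2 -2.53, CPA4 -2.41, EIF5A2 -2.07, E2F7 -1.91, PGD -1.69, UHMK1 -1.49, STIP1 -1.46, TULP3 -1.43, CDK8 -1.36, FOXM1 -1.29, JMJD8 -1.29, H2BC11 -1.17, NOP58 -1.13, MKI67 -1.11, CD68 -1.10, RRM2B -1.10, CA2 -1.09, HSF1 -1.08, GINS2 -1.06, TFRC -1.03, RB1 -0.93, PHLDA2 -0.83, NDUFAB1 -0.69, RBL1 -0.64, CENPA -0.64, SYVN1 -0.61, IGF1R -0.60, TFDP1 -0.58, CSRP2 -0.57, NDUFB10 -0.54, FZD3 -0.46, CANX -0.45 and FTL -0.43. The 21 higher with siH19-2 were ARRDC3 3.73, PRSS8 2.98, SS18 2.87, FRK 2.82, NR4A2 2.73, PTBP2 2.64, CYP24A1 2.35, LIPH 2.07, CDH1 1.65, NETO2 1.24, ITGAV 1.02, MED13 1.02, SLC2A3 1.01, ARRDC4 0.98, CCN1 0.97, RPS19 0.92, CDK19 0.81, RICTOR 0.81, BNIP3L 0.73, IGF2BP3 0.62 and PLAGL1 0.44.

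Among 2370 array rows outside the transcript clusters that passed the filter, 27 differed from control in the mean of both siRNAs, 40 with siH19-1 and 320 with siH19-2 (68 higher and 252 lower), and 424 differed between the siRNAs (103 higher and 321 lower with siH19-2).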

How the results depend on the processing

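Scaling to the control probes, counting identical values once and dividing the control arrays between the siRNAs were chosen after the data were seen, and the other alternatives before. The total counts of transcript clusters stayed within 1.5 times under array weights, robust eBayes, eBayes without trend, the filter at log2 6, scaling to the control probes and identical values counted once. Scaling to the control probes moved the split by direction further, from 1282 higher and 1772 lower to 765 and 3273 for the mean of both siRNAs and from 2527 and 2676 to 1246 and 4996 with siH19-2. The mean of these controls also differed between replicates of a group. List counts were not computed under array weights, the other eBayes settings or identical values counted once. The replicate block moved no count by more than 1.5 times except opposite directions (115), and among named genes and lists it changed no call other than the 10 gene and 4 list calls given with it in the results. Its counts were 4090 for the mean of both siRNAs, 2142 with siH19-1, 6581 with siH19-2, 5983 between the siRNAs and 1192 in the same direction. With no filter the counts were 1489 for the mean of both siRNAs, 607 with siH19-1, 3108 with siH19-2, 2667 between the siRNAs, 329 in the same and 11 in opposite directions, with more clusters tested. A fit of only the groups compared gave 557 with siH19-1, 3434 with siH19-2, 296 in the same and 12 in opposite directions, with fewer arrays. Opposite directions numbered 114 with quantile normalization and 129 with median centring, and a required fold of 1.5 left 1982 for the mean of both siRNAs. The filter at log2 6 gave 3 lists and no filter 10 lists between the siRNAs. List calls numbered 0, 0, 0 and 0 with an estimated correlation (mean, siH19-1, siH19-2, difference) and 0, 0, 3 and 1 with fry, with 0 lists and 11, 7, 12 and 10 lists at an unadjusted p under 0.05.

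Leaving out 1 array, where a lone array is assumed to vary like the other groups, gave 636 to 1772 for the mean of both siRNAs, 0 to 770 with siH19-1, 1285 to 3655 with siH19-2, 517 to 4760 between them, 0 to 487 in the same and 0 to 11 in opposite directions. Limma's 0 without siH19-1 replicate 1 or 2 stood beside 3939 and 3805 clusters at an unadjusted p under 0.05. Lists between the siRNAs ranged from 2 to 6. Of 211 gene results, 93 were called for the mean of both siRNAs, 26 with siH19-1, 37 with siH19-2 and 26 between the siRNAs. Only these had a call to lose, and some were lost without each of the 6 arrays, most often without a siH19-1 array. Arrays of a group not compared enter only through the estimate of the spread.

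H19 changed sign without passing in any alternative. Its log2 fold change was -0.115, -0.048, -0.182 and -0.134 with scaling to the control probes (mean, siH19-1, siH19-2, difference), and the difference was -0.011 with quantile normalization and -0.030 with median centring. Leaving out 1 array gave -0.055 to 0.145, -0.075 to 0.125, -0.035 to 0.165 and -0.005 to 0.085. ACTA2 became -0.055 with scaling to the control probes. Without passing, the test changed sign for imprinted genes with no filter (adjusted p = 0.816) and the filter at log2 6 (0.864), let-7 targets with no filter (0.977) and fry (0.669), and the IGF list with fry (0.808). Leaving out 1 array also changed it for RNA silencing (0.799 to 0.998), oxidative phosphorylation (0.42 to 0.873), let-7 targets (0.66 to 0.956) and EMT genes (0.438 to 0.956). Except where the number of clusters or arrays changed, the cause was not tested. Whether signal in the range of background limits the comparison of H19 stays open, at a mean of 4.95 against medians of 3.00 for background probes and 3.72 for marker genes of other cell types. Means of background probe rows reached 5.99.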

Other observations

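The test in this part was chosen after the result was seen. With siH19-2, protein-coding clusters and clusters without a gene symbol moved apart. Of 9891 protein-coding clusters 1082 were higher and 1820 lower than control (median log2 fold change -0.07), and of 12172 unnamed clusters 1217 were higher and 691 lower (median 0.11). Scaling to the control probes shifts the median of all clusters by -0.25, so these directions are relative to the other clusters. Long noncoding RNA clusters were higher in 40 and lower in 12 of 367 cases, microRNA clusters in 21 and 5 of 323, and small nucleolar RNA clusters in 9 and 1 of 155. The split was less uneven for pseudogenes (19 higher and 15 lower of 490) and transcribed pseudogenes (28 and 15 of 307). Of 20 small nuclear RNA clusters 0 were higher and 2 lower. With siH19-1 the split was 417 higher and 558 lower for protein-coding, 203 and 284 for unnamed and 2 and 10 for long noncoding RNA clusters. It was 2 and 0 for microRNA and 2 and 1 for small nucleolar RNA clusters. Directly compared, 44 long noncoding RNA clusters were higher and 4 lower with siH19-2 than with siH19-1.

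The medians of the unnamed and the protein-coding clusters differed by 0.19 in replicate 1 and 0.17 in replicate 2. A bias that depends on signal level is argued against as the whole cause, since the difference was positive in each of 6 level bins, from 0.12 to 0.26, and above 2 bootstrap SE in each. The bootstrap resampled clusters, which are not independent replicates, so its SE holds no spread between arrays. Whether the unnamed clusters are noncoding, and differences between the classes in probe design or RNA fraction, were not tested, and no biological explanation was tested.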
